A study of Rattus norvegicus with 6 samples.

How the data were processed

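Single-nucleus RNA sequencing was done on ventricles of uninjured hearts from wild-type female rats aged 8 weeks, per the labels. The 3 inbred strains BN-Lx, F344 and M520 belong to the Hybrid Rat Diversity Panel, a collection of inbred rat lines used for genetic mapping, and 2 hearts per strain gave 6 libraries. Hearts were perfused with collagenase, ventricular tissue was lysed and homogenised, and nuclei labelled with the DNA dye DAPI were sorted by flow cytometry before loading on the 10x Genomics 3' chemistry, per the labels' protocols. The sorting gate, the day of each collection and the order of library preparation were not given in the sources used here. Reads were processed with Cell Ranger 9.0.0 against the genome build mRatBN7.2, per the submitters' processing notes. That build is the assembly of a Brown Norway rat and is therefore closer to BN-Lx than to F344 or M520. The gene annotation, the treatment of intronic reads and the rule that called nuclei were not given in the sources used here.

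The deposited files held raw UMI counts of 34034 genes in 35276 barcodes, each library in its own matrix, and every deposited barcode held at least 500 UMIs. A gene table of the later assembly GRCr8 held 29433 of the 34034 symbols (86.5%) and was used only for names and for which genes neighbour each other. Barcodes with at least 500 UMIs, at least 300 genes and at most 5% mitochondrial UMIs passed, which left 6072 and 5159 in BN-Lx replicates 1 and 2, 3846 and 8220 in F344, and 4733 and 5213 in M520. Scrublet scores, run through scanpy, then removed a share of barcodes set by the loading rule of 0.8% per 1000 nuclei (3.08% to 6.58% expected), because Scrublet's automatic thresholds marked between 0.0423% and 14.9% of a library. This removed 287, 201, 94, 507, 178 and 173 barcodes in that order and kept 5785, 4958, 3752, 7713, 4555 and 5040 nuclei, 31803 in total. Median UMIs per kept nucleus were 1209 and 2335.5 in BN-Lx, 1415 and 1388 in F344 and 1217 and 2300 in M520, median genes were 825, 1358.5, 946, 934, 823 and 1346, and median mitochondrial shares lay between 0.535% and 1.28%. Xist was counted 32307 to 91259 times per library and Y-linked genes 0 to 4 times, as labelled for females.

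Counts were scaled and log-transformed in scanpy 1.11.5, and 2000 variable genes chosen per library gave 30 principal components, a graph of 15 neighbours and Leiden clusters at resolution 1 (leidenalg 0.10.2, igraph 0.11.9). Clusters were named from marker lists fixed for 12 cell types plus red blood cells, none of which entered as a test between strains except where stated. A cluster took the name of the type whose markers stood highest, given at least 3 markers up. By rule, a cluster with Mki67 or Top2a among its 10 leading genes took no name. Of the 31 clusters, 10 stayed unnamed, 9 because at least 10% of their barcodes had been called doublets and 1 because fewer than 3 markers were up, and the remaining clusters formed 11 classes with 29953 nuclei. Class names therefore mean nuclei resembling that type. The rule for naming clusters was revised once and the doublet limit for mixed clusters lowered from 15% to 10% after the first clusters had been seen.

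UMI counts were summed per library over the nuclei of a class, since nuclei of a heart are not independent replicates, and n was 2 hearts per strain throughout. The cardiomyocyte-like, fibroblast-like, endothelial-like, pericyte-like and macrophage-like classes held at least 50 nuclei in every library and were tested. Each class was fitted with edgeR 4.0.16 (quasi-likelihood test, TMM normalisation, filterByExpr, R 4.3.3) on all 6 libraries, with strain as the only term and 3 residual degrees of freedom, and the 3 contrasts between strains were adjusted by the Benjamini-Hochberg method. A gene was called at an adjusted p below 0.05. Unless stated otherwise, adjusted p-values below come from this test, log2 changes carry its standard error, and gene levels are TMM-scaled CPM given as mean ± SD of 2 hearts. The p-values measure the spread between hearts, while binomial and Poisson intervals (95%) cover counting error only. For a gene with no counts in a strain a lower bound of the fold was computed against a floor of 3 counts over that strain's libraries, and with 1 to 3 counts the ratio of summed counts over summed library sizes is given with its counting interval, so that it differs from the ratio of the mean CPM. On data simulated from these libraries with 200 changed genes, the F344 and BN-Lx contrast recovered 15.3% of 2-fold and 83.7% of 4-fold changes among 12241 cardiomyocyte-like genes, with 5.83% of calls false. These shares were 22.2% and 82.8% of 10909 fibroblast-like genes (4.59% false) and 26.8% and 86.6% of 11305 endothelial-like (8.33%). They were 15.4% and 72.0% of 7004 pericyte-like (3.57%) and 6.38% and 69.9% of 7949 macrophage-like genes (2.74%).

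In cardiomyocyte-like nuclei, 19 gene lists were tested with camera (limma 3.58.1, preset correlation 0.01), adjusted over lists and contrasts. They covered the cell cycle (G1/S, G2/M, inhibitors and ploidy regulators), actomyosin with Shroom partners, the intercalated disc, the sarcomere, wall stress, calcium handling, fatty acid oxidation, glucose metabolism, nuclear-encoded and mitochondrial-genome oxidative phosphorylation, YAP targets, the circadian clock, immediate early and dissociation stress genes, antigen presentation and interferon, extracellular matrix, ribosomal proteins and the genes near Shroom3. The same lists in the other classes, markers of other cell types in cardiomyocyte-like nuclei and 3 further lists (glucocorticoid receptor targets and 2 arms of the clock) were added after the data had been seen. Class sizes were compared with edgeR on nuclei per library, 11 classes. A strain difference was tested for a difference between cardiomyocyte-like and endothelial-like nuclei as an interaction on 12 class sums of the 6 hearts, with 1 term per heart. The ratio of median UMIs in cardiomyocyte-like to other nuclei was compared by an exact permutation test over the 15 splits of the 6 libraries into pairs.

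The strain groups, tests, lists, markers, alternatives and the rule for genes named were chosen before the data were examined. Among genes called with a log2 change of at least 1 either way, libraries of both strains apart, a mean of at least 10 CPM and a proper symbol, the rule took the 8 highest and 8 lowest changes per cardiomyocyte-like contrast and 4 each in other classes, plus up to 3 members per list with the smallest p, and Shroom3. Genes named outside it, chosen after their values were seen, are those called in all 5 classes, other called members of lists, Tsc22d3, Kdr, genes heading clusters and those of the closing section. Some genes that the rule selects are not reported here. Alternatives were DESeq2 1.42.0 size factors and Wald test, no filter or a filter of 5 CPM in 2 libraries on low counts, fits of only the strains compared, counts thinned to equal depth, doublet calls kept, a stricter nuclei filter (1000 UMIs, 500 genes, 1% mitochondrial), classes by marker score, each library left out, and the replicate number as a block. Fits without single cardiomyocyte-like clusters and an interaction with replicate number by class were added later.

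Whether replicate numbers pair the libraries was checked before the fits were compared. In cardiomyocyte-like nuclei, deviations from the strain means correlated at 0.407 between BN-Lx and F344, 0.338 between BN-Lx and M520 and 0.325 between F344 and M520, so libraries of the same number were treated as paired in the fit with the replicate block, although the labels do not say what the numbers mark. Tests for outlying libraries and of gene counts under other splits of the libraries were not made, because each strain had only 2 libraries. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 did the remaining steps, with a random seed of 0.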

Results

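Gene expression was measured in single nuclei from the ventricles of 8-week-old female rats of 3 inbred strains, BN-Lx, F344 and M520, with 2 hearts per strain and 1 library per heart. The series title ties the study to a genetic mapping of cardiomyocyte ploidy, the number of genome copies per cell, and to Shroom3, an actin-binding protein that guides contraction of the apical cell surface. The libraries held 12325960 and 17370285 UMIs in BN-Lx, 8244302 and 19366049 in F344 and 8898892 and 19399367 in M520. Of the 31803 nuclei kept, 8002 resembled cardiomyocytes. Unnamed nuclei made up 4.25% and 4.28% of BN-Lx, 9.89% and 3.94% of F344 and 7.79% and 7.18% of M520.

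Cardiomyocyte-like nuclei made up 16.8% ± 11.7 of the kept nuclei in BN-Lx (SD, n = 2), 31.5% ± 2.77 in F344 and 27.1% ± 2.00 in M520. Endothelial-like nuclei made up 37.0% ± 5.03, 26.5% ± 4.11 and 30.6% ± 0.479, and fibroblast-like nuclei 20.8% ± 5.02, 16.2% ± 2.52 and 16.4% ± 2.502. Pericyte-like nuclei made up 9.40% ± 0.0563 in BN-Lx, 4.95% ± 1.08 in F344 and 7.82% ± 0.222 in M520. The 2 BN-Lx hearts lay apart, with 25.1% (95% binomial interval 24.0 to 26.2) and 8.51% (7.75 to 9.32) cardiomyocyte-like nuclei.

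**Figure D1:**
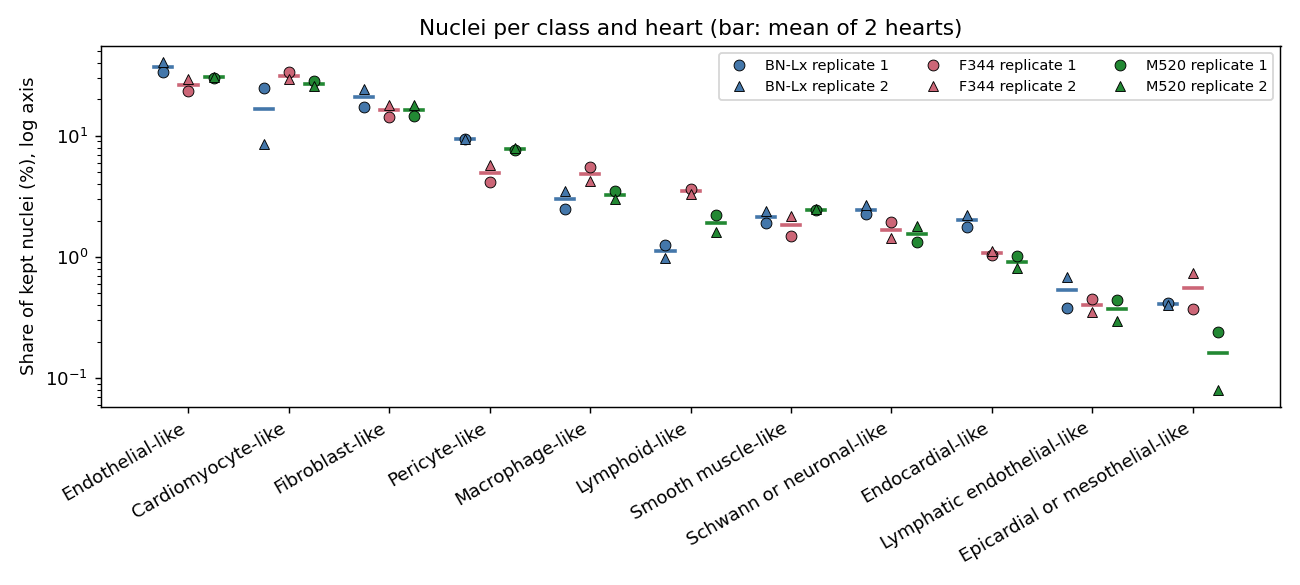
Share of kept nuclei in each class (percent, log axis) by strain, with a circle for replicate 1, a triangle for replicate 2 and a bar at the mean. Cardiomyocyte-like nuclei made up 8.51% in BN-Lx replicate 2 against 25.1% or more in the other libraries.

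Lymphoid-like nuclei were more common in F344 (3.49% ± 0.235) than in BN-Lx (1.12% ± 0.181), a log2 difference of 1.63 (SE 0.29, adjusted p = 3.4e-05, edgeR on nuclei per class). A cluster with Skap1, Cd247 and Themis held 61 and 40 of them in the BN-Lx hearts, 137 and 253 in F344 and 100 and 80 in M520. A cluster with the B-cell genes Pax5, Bank1 and Ms4a1 held 11 and 9, 0 and 3, and 2 and 1, so that the rise lay in the former. The shares of cardiomyocyte-like nuclei (log2 0.91, SE 0.36, adjusted p = 0.0392) and macrophage-like nuclei (0.69, SE 0.27, adjusted p = 0.0392) were also higher in F344. The cardiomyocyte-like call was lost with TMM over classes (adjusted p = 0.0978), the stricter nuclei filter (0.405) and marker scores (0.3325), and the macrophage-like call with the latter 2 (0.365 and 0.234). Pericyte-like (-0.92, SE 0.28, adjusted p = 0.0124) and endocardial-like nuclei (-0.88, SE 0.33, adjusted p = 0.0392) were less common in F344. In M520 the endocardial-like share was lower than in BN-Lx (0.912% ± 0.139 against 2.00% ± 0.336, log2 -1.13, SE 0.33, adjusted p = 0.0194). The cardiomyocyte-like share was 0.69 log2 higher in M520 than in BN-Lx without passing the test (adjusted p = 0.147) and passed it with the replicate block (0.83, adjusted p = 0.0278). Between M520 and F344 edgeR called none of the 11 classes. With the replicate block the lymphoid-like share was lower (adjusted p = 0.0403) and the pericyte-like share higher in M520 than in F344 (0.66, adjusted p = 0.0403), against -0.86 (adjusted p = 0.0514) and 0.65 (adjusted p = 0.0906) without it. Of the 5 classes called between F344 and BN-Lx, only the lymphoid-like class stayed past the test whichever library was left out. The endocardial-like call in M520 was kept, among libraries left out, only without BN-Lx replicate 1. The stricter nuclei filter ended it (adjusted p = 0.479) and the pericyte-like call in F344 (0.0581). Nuclei were sorted and gated on UMIs, either of which can set class shares.

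Within the cardiomyocyte-like class a cluster led by the heat shock genes Dnajb1 and Cryab and the stress genes Atf3 and Ankrd1 held 52.2% and 26.3% of the cardiomyocyte-like nuclei of the BN-Lx hearts, 24.9% and 16.8% in F344 and 31.4% and 26.7% in M520. A cluster with low UMIs held 31.8% of them in BN-Lx replicate 2 and between 0.526% and 3.54% in the other libraries. A small cluster led by the interferon-induced genes Gbp1 and Irgm held 23 and 14 nuclei of the F344 hearts, 6 and 5 of the M520 hearts and 0 of 1452 and 0 of 422 in BN-Lx.

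Shroom3 was a cardiomyocyte transcript in these libraries. In cardiomyocyte-like nuclei it reached 791 ± 27.6 CPM in BN-Lx, 922 ± 71.4 in F344 and 680 ± 112 in M520 (plain CPM, SD, n = 2), from 1583 to 8821 UMIs per library. Mean CPM in BN-Lx, F344 and M520 was 15.97, 29.9 and 11.6 in endothelial-like and 42.9, 37.7 and 37.0 in fibroblast-like nuclei. It was 21.1, 48.7 and 23.0 in pericyte-like and 66.0, 105 and 105 in macrophage-like nuclei. Per library Shroom3 lay at 0.951% to 20.0% of its cardiomyocyte-like level in these 4 classes. The median of 10 cardiomyocyte marker genes in the same nuclei, as a share of their own cardiomyocyte-like level, was lower than that of Shroom3 in all 6 libraries in fibroblast-like nuclei (1.27% to 4.11% against 3.20% to 6.49%) and pericyte-like nuclei (1.13% to 3.99% against 1.72% to 5.45%). In endothelial-like nuclei it was lower in 4 libraries and higher in 2 (0.948% to 3.81% against 0.951% to 4.22%). In macrophage-like nuclei it ranged from 8.62% to 22.7% against 6.07% to 20.0%.

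**Figure D2:**
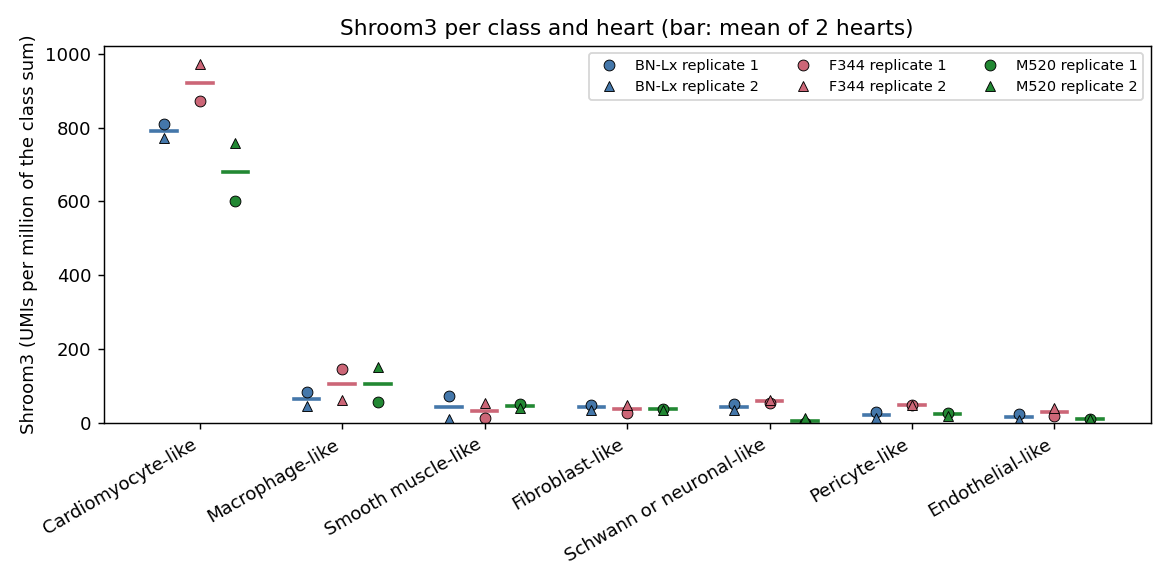
Shroom3 in CPM (linear axis from 0) per library and class, with a circle for replicate 1, a triangle for replicate 2 and a bar at the mean. Cardiomyocyte-like nuclei held 601 to 973 CPM.

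No strain contrast of Shroom3 passed the test in cardiomyocyte-like nuclei. The log2 difference was 0.18 between F344 and BN-Lx (SE 0.22, 95% interval -0.31 to 0.66, adjusted p = 0.781), -0.30 between M520 and BN-Lx (SE 0.22, -0.78 to 0.19, adjusted p = 0.714) and -0.47 between M520 and F344 (SE 0.22, -0.96 to 0.01, adjusted p = 0.483). With the replicate block Shroom3 was lower in M520 than in F344, by -0.48 (adjusted p = 0.0415). In the other tested classes Shroom3 passed in no contrast with all 6 libraries, the filter on low counts and no block. The largest differences were 1.27 in pericyte-like nuclei between F344 and BN-Lx (SE 0.50, adjusted p = 0.267, and 1.38, adjusted p = 0.0391, with the block) and -1.43 in endothelial-like nuclei between M520 and F344 (SE 0.51, adjusted p = 0.202, and -1.50, adjusted p = 0.0394, with the block). Without a filter on low counts that endothelial-like difference also passed (-1.42, adjusted p = 0.00628). Without BN-Lx replicate 1 or 2 it was -1.44 or -1.45, and F344 against BN-Lx 1.99 or 0.32 (1.04, adjusted p = 0.270, with all). Both classes held 6 to 102 Shroom3 UMIs per library and most cardiomyocyte marker RNA in F344, so carried-over RNA is not excluded. In fibroblast-like nuclei the 3 differences lay between -0.23 and -0.11 and in macrophage-like nuclei between 0.07 and 0.78.

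Of 20 measured genes near Shroom3, 3 passed the test in cardiomyocyte-like nuclei, each between M520 and another strain. Fras1, which encodes a basement membrane protein, had 57.2 ± 21.5 CPM in BN-Lx, 40.4 ± 5.90 in F344 and 5.92 ± 0.566 in M520, a fall of -3.26 log2 against BN-Lx (SE 0.34, adjusted p = 7.2e-04) and -2.79 against F344 (SE 0.33, adjusted p = 0.0019). G3bp2, a stress granule protein, was highest in M520 (632 ± 85.5 CPM against 303 ± 42.5 and 209 ± 31.8), up 1.06 log2 on BN-Lx (SE 0.23, adjusted p = 0.0472) and 1.60 on F344 (SE 0.24, adjusted p = 0.00748). Parm1 was lower in M520 than in F344 (325 ± 25.6 against 673 ± 86.5 CPM, log2 -1.05, SE 0.22, adjusted p = 0.0473). Against BN-Lx its difference was -0.97 (adjusted p = 0.0574, and 1.2e-04 with the block). Adjusted over the list alone, 1 of the 20 was higher and 2 lower in M520 than in BN-Lx, 2 higher and 3 lower than in F344, and none differed between F344 and BN-Lx, where edgeR also called 0 and the list's median was 0.03. The G3bp2 call against BN-Lx was lost without BN-Lx replicate 2 (adjusted p = 0.140), F344 replicate 1 (0.0621), F344 replicate 2 (0.0776), M520 replicate 1 (0.138) or M520 replicate 2 (0.343), and that against F344 without F344 replicate 2 (0.145) or M520 replicate 2 (0.0904). The Parm1 call was lost without F344 replicates 1 or 2 (0.142 and 0.353) or M520 replicates 1 or 2 (0.295 and 0.358).

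In cardiomyocyte-like nuclei the unconventional myosin Myo5c had 61.1 ± 0.259 CPM in F344 against 0.0995 in BN-Lx (ratio of summed counts 453, counting interval 81.1 to 17920, adjusted p = 6.0e-05), and the kinase Cdkl1 37.8 against 0.299 (ratio 80.5, interval 27.4 to 392, adjusted p = 9.0e-04). Agbl4, an enzyme that trims glutamates from tubulin, fell from 161 ± 37.6 to 6.81 ± 2.04 CPM (log2 -4.63, SE 0.53, adjusted p = 0.00109), and beta-tropomyosin Tpm2 from 362 ± 109 to 58.8 ± 9.54 CPM (-2.63, SE 0.27, adjusted p = 6.9e-04). The transcription factor Plagl1 (log2 4.59, SE 0.56), the ankyrin-binding adhesion protein Nfasc (4.33, SE 0.52) and the protocadherin Pcdh15 (4.33, SE 0.53) were higher in F344. Eqtn (-3.19, SE 0.37), the sugar transporter family member Slc35c2 (-2.82, SE 0.27), Ldlrad3 (-2.71, SE 0.30), the scaffold protein Disc1 (-2.62, SE 0.28), the vitamin D hydroxylase Cyp2r1 (-2.60, SE 0.33) and the DNA ligase Lig4 (-2.52, SE 0.35) were lower. The class I genes RT1-A3 (ratio 71.7, interval 24.3 to 349, adjusted p = 5.6e-04) and RT1-CE5 (ratio 53.0, interval 14.5 to 441, adjusted p = 0.00124) and the pseudogene Cd36-ps1 (log2 4.72, SE 0.35) were higher too, but reads of these families can be split among near-identical copies and their changes are uncertain.

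Antigen presentation and interferon genes formed the group that stood highest in F344 against BN-Lx. Of 18 measured members, 7 rose, among them B2m (log2 1.86, SE 0.35, adjusted p = 0.0190), Irf1 (2.30, SE 0.49), the peptide transporter Tap2 (3.24, SE 0.66), the immunoproteasome subunit Psmb9 (4.81, SE 0.98), RT1-A2 (2.98, SE 0.47) and RT1-CE5. Adjusted over the list alone, 12 rose. The list's median was 1.96, with 17 of 18 above 0 (camera adjusted p = 2.9e-12, adjusted p = 0.898 with an estimated correlation). Immediate early and dissociation stress genes lay lower in F344, with a median of -0.73, 4 of 26 above 0 and camera adjusted p = 6.4e-06 (adjusted p = 0.898 with an estimated correlation). Of them the chaperone Hsph1 fell (-1.80, SE 0.35, adjusted p = 0.0216), and 12 fell adjusted over the list alone. The chaperone Hspa1b (-1.36, SE 0.33) had an adjusted p of 0.0674 (1.2e-05 with the block) and Egr1 (-1.32) one of 0.0693 (0.00208 with the block). The cluster led by stress genes held a larger share of BN-Lx replicate 1 than of any other library. In nuclei of the largest cardiomyocyte-like cluster alone this list no longer passed (adjusted p = 0.149), and Egr1 changed sign, to 0.55. Without the stress-led cluster Egr1 changed sign too (log2 0.0875), while the list passed (adjusted p = 0.0150).

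Nuclear-encoded oxidative phosphorylation lay slightly lower in F344 (median -0.28, 6 of 31 above 0, camera adjusted p = 0.0140, 0.898 as adjusted p with an estimated correlation). Its member Uqcrc2, a core subunit of complex III, fell from 303 ± 82.0 to 135 ± 1.72 CPM (log2 -1.17, SE 0.25, adjusted p = 0.0368) and was the 1 call adjusted over the list alone. Calcium handling and ion channel genes had a median of -0.20 with 6 of 25 above 0 (camera adjusted p = 0.0471, and adjusted p = 0.898 with an estimated correlation). Kcnip2, the subunit of the transient outward potassium channel, fell from 728 ± 14.7 to 362 ± 8.71 CPM (-1.01, SE 0.21, adjusted p = 0.0300), again the 1 call adjusted over the list alone. Of 28 sarcomere genes the M-band protein Myom3 rose (1.70, SE 0.29, from 9.34 ± 0.541 to 30.04 ± 2.57 CPM, adjusted p = 0.0132), and of 30 fatty acid oxidation genes Ech1 rose (1.37, SE 0.30, adjusted p = 0.0402). These lists did not pass (medians -0.04, with a mean of 0.02, and 0.24, camera adjusted p = 0.992 and 0.186). G1/S genes had a median of 0.01 over 15 members (adjusted p = 0.992), G2/M genes 0.45 over 5 (adjusted p = 0.460) and cell cycle inhibitors and ploidy regulators 0.07 over 23 (adjusted p = 0.694, where the mean was -0.04 and the test pointed down). The remaining lists did not pass either, with medians of 0.03 for actomyosin and Shroom partners (adjusted p = 0.904, the test pointing down), -0.08 for the intercalated disc (0.691), -0.21 for wall stress (0.386) and -0.16 for glucose metabolism (0.346). The others lay at -0.23 for the mitochondrial genome (0.419), -0.24 for YAP targets (0.626), -0.18 for the clock (0.360), -0.51 for extracellular matrix (0.198), -0.17 for ribosomal proteins (0.386) and 0.03 for the genes near Shroom3 (0.889, the test pointing down). Extracellular matrix passed downwards without BN-Lx replicate 1 and wall stress without BN-Lx replicate 2. The 10 endothelial markers in these nuclei were all lower in F344 (median -1.11, camera adjusted p = 0.00575, and 0.856 with an estimated correlation), none called singly. RNA carried over from other nuclei was not tested, and BN-Lx replicate 2 held 40.6% endothelial-like nuclei. Leaving out BN-Lx replicate 2, F344 replicate 1 or M520 replicate 2 ended the list call for calcium handling (adjusted p = 0.0935, 0.176 and 0.0664), and leaving out BN-Lx replicate 1 or F344 replicate 2 that for oxidative phosphorylation (0.196 and 0.257). Without BN-Lx replicate 2, F344 replicates 1 and 2 and M520 replicates 1 and 2 in turn, Kcnip2 had adjusted p = 0.0579, 0.197, 0.227, 0.0655 and 0.0648 and Uqcrc2 0.119, 0.208, 0.223, 0.0516 and 0.0516. Ech1 had 0.136, 0.211, 0.0679, 0.0626 and 0.0609 without BN-Lx replicate 1, F344 replicates 1 and 2 and M520 replicates 1 and 2. Myom3, Hsph1 and Lig4 lost their calls without F344 replicate 2 (0.0895, 0.168 and 0.0541).

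In all, edgeR called 313 of 12550 genes between F344 and BN-Lx in cardiomyocyte-like nuclei, 205 higher and 108 lower in F344, and 1733 (865 higher and 868 lower) with the replicate block. Without BN-Lx replicate 1 the direction turned, with 210 higher and 243 lower. The count was 190 without F344 replicate 1 and 137 without F344 replicate 2, where a strain's lone library, here and below, is assumed to vary like the other groups.

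In cardiomyocyte-like nuclei Ooep, an oocyte factor, had 48.1 ± 4.80 CPM in M520 and no counts in the other strains, at least 119-fold higher than in BN-Lx (adjusted p = 1.7e-04). Irak2, a kinase of interleukin-1 and Toll-like receptor signalling, fell from 78.0 ± 5.88 to 3.82 ± 0.403 CPM (log2 -4.37, SE 0.27, adjusted p = 5.3e-05). Cdkl1 was higher in M520 (ratio 43.3, interval 14.6 to 212, adjusted p = 0.00366). Tpm2 fell to 45.3 ± 6.06 CPM (-3.01, SE 0.28, adjusted p = 3.9e-04) and Agbl4 to 7.44 ± 6.91 CPM (-4.64, SE 0.54, adjusted p = 0.00135). Plagl1 (4.79, SE 0.56) and Ccbe1, needed for lymphatic vessel growth (3.97, SE 0.59), were higher in M520. The RNA-binding protein Igf2bp3 (-3.23, SE 0.44), the lipid enzyme Cds1 (-2.98, SE 0.32), the microtubule protein Map1a (-2.95, SE 0.53) and the myosin Myo5b (-2.71, SE 0.37) were lower. RT1-A2 (4.81, SE 0.43), RT1-A3 (ratio 34.4, interval 11.5 to 169), RT1-CE5 (ratio 30.2, interval 8.11 to 254) and Cd36-ps1 (4.30, SE 0.35) were higher with the same uncertainty of shared reads.

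Of the 19 lists, antigen presentation and interferon (median 1.00, 15 of 18 above 0, camera adjusted p = 8.8e-07) and immediate early and stress genes (median -0.66, 4 of 26 above 0, adjusted p = 1.0e-04) passed between M520 and BN-Lx, both with adjusted p = 0.898 with an estimated correlation. In the first RT1-A2 and RT1-CE5 rose, and 5 members adjusted over the list alone. In the second Hsph1 fell (-1.66, SE 0.35, adjusted p = 0.0361), and 6 members adjusted over the list alone. Without the cluster led by stress genes the second list had an adjusted p of 0.414, in the largest cluster alone 0.601 and without BN-Lx replicate 1 0.0684. Calcium handling genes had a median of -0.16 (camera adjusted p = 0.101, and 0.0143 with the block), of which 2 fell adjusted over the list alone and none over all genes. The pacemaker channel Hcn2 stood at -1.37 (adjusted p = 0.0600, and 1.2e-05 with the block) and junctophilin Jph2 at -1.06 (adjusted p = 0.108, and 6.1e-04 with the block). The lists that did not pass had medians of 0.32 for G1/S (adjusted p = 0.734), -0.61 for G2/M (0.552), 0.02 for cell cycle inhibitors and ploidy regulators (0.992, the test pointing down), -0.12 for actomyosin and Shroom partners (0.552), -0.09 for the intercalated disc (0.415), -0.18 for the sarcomere (0.255) and -0.18 for wall stress (0.419). Further medians were -0.12 for fatty acid oxidation (0.666), -0.09 for glucose metabolism (0.552), -0.09 for nuclear-encoded oxidative phosphorylation (0.439), 0.12 for the mitochondrial genome (0.562, where the mean was -0.20), and -0.20 for YAP targets (0.613). The last were -0.04 for the clock (0.694), -0.53 for extracellular matrix (0.613), -0.08 for the genes near Shroom3 (0.562) and 0.03 for ribosomal proteins (0.587). The calls of Hsph1 were lost without BN-Lx replicate 1, M520 replicate 1 or M520 replicate 2 (adjusted p = 0.0802, 0.176 and 0.262), and those of Map1a, Myo5b and RT1-CE5 without M520 replicate 2 (0.149, 0.0651 and 0.0526).

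This contrast called 254 of 12550 genes, 146 higher and 108 lower in M520, and 1041 (482 higher and 559 lower) with the replicate block. Without BN-Lx replicate 1 the direction turned, with 132 higher and 192 lower. The count was 403 without BN-Lx replicate 2, 119 without M520 replicate 1 and 97 without M520 replicate 2.

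Fkbp5, Zbtb16 and Tsc22d3 respond to glucocorticoid hormones in many tissues. In cardiomyocyte-like nuclei Fkbp5, a chaperone that dampens the glucocorticoid receptor, had 78.1 ± 31.3 CPM in M520, 10.9 ± 2.61 in F344 and 22.6 ± 0.999 in BN-Lx (M520 against F344 log2 2.88, SE 0.33, adjusted p = 0.00146). The transcription factor Zbtb16 had 2183 ± 569, 328 ± 206 and 1015 ± 52.2 CPM in the same order (2.74, SE 0.40, adjusted p = 0.00748). Both passed in all 5 classes, Fkbp5 with log2 differences of 1.86 to 3.55 and Zbtb16 with 2.74 to 4.87. Tsc22d3 was higher in M520 in fibroblast-like (2.19, adjusted p = 0.0132) and macrophage-like nuclei (1.96, adjusted p = 0.0469). It stood at 1.01 in cardiomyocyte-like (adjusted p = 0.291), 1.23 in endothelial-like (adjusted p = 0.111) and 2.85 in pericyte-like nuclei (adjusted p = 0.0641).

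**Figure D3:**
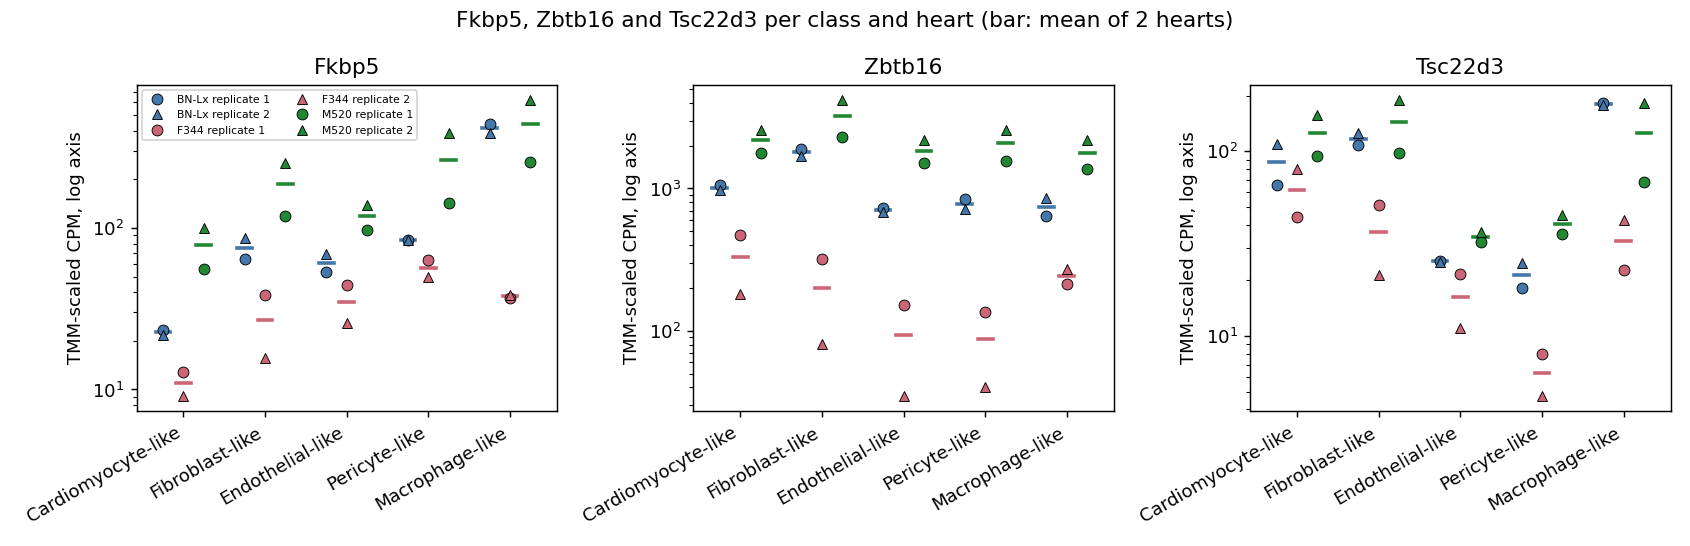
Fkbp5, Zbtb16 and Tsc22d3 in TMM-scaled CPM (log axis) in 5 classes by strain, with a circle for replicate 1, a triangle for replicate 2 and a bar at the mean. In cardiomyocyte-like nuclei Zbtb16 averaged 328 CPM in F344 and 2183 CPM in M520.

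Bckdhb, a subunit of the complex that degrades branched-chain keto acids, had 951 ± 225 CPM in M520 against 146 ± 1.61 in F344 (log2 2.70, SE 0.24, adjusted p = 5.2e-04) and differed by 2.36 to 2.95 in all 5 classes. Ooep was at least 207-fold higher in M520 than in F344 (adjusted p = 1.5e-04) and Myo5c at least 202-fold lower (adjusted p = 5.3e-05). The dynein adaptor Bicd1 (2.84, SE 0.40), Lig4 (2.70, SE 0.35), the Golgi protein Cog2 (2.46, SE 0.27) and the histone gene H4cl1 (2.43, SE 0.31), whose reads near-identical histone copies may share, were also higher. Pcdh15 (-3.90, SE 0.50), Irak2 (-3.59, SE 0.27, adjusted p = 1.5e-04), the kinase Pak5 (-3.44, SE 0.33), the sodium-proton exchanger Slc9a9 (-3.29, SE 0.43), Cds1 (-3.11, SE 0.31), the vesicle protein Synpr (-3.08, SE 0.26, 138 ± 11.9 to 16.5 ± 3.50 CPM) and Nfasc (-2.94, SE 0.43) were lower in M520.

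Fatty acid oxidation genes lay lower in M520 than in F344 (median -0.28, 9 of 30 above 0, camera adjusted p = 0.0249, adjusted p = 0.898 with an estimated correlation). Of them Ucp3, the mitochondrial carrier of muscle, fell from 67.0 ± 13.7 to 20.4 ± 7.39 CPM (log2 -1.68, SE 0.31, adjusted p = 0.0242), the 1 call adjusted over the list alone, while Acadm stood at -0.85 (adjusted p = 0.146, and 0.00263 with the block). Antigen presentation genes had a median of -0.83 with 4 of 18 above 0 (camera adjusted p = 0.0249, and 0.0676 with the block), with RT1-A2 higher (1.82, SE 0.30, adjusted p = 0.0130) and Tap2 lower (-2.81, SE 0.59, adjusted p = 0.0450). Adjusted over the list alone, 1 was higher and 3 lower. Ribosomal protein genes lay higher (median 0.37, 24 of 28 above 0, camera adjusted p = 0.0376, and 0.0752 with the block), with no member called. Of the 5 G2/M genes measured all were lower (median -0.91, camera adjusted p = 0.0441, and 0.135 with the block), with Mki67, a marker of cycling cells, at 5.26 ± 0.470 CPM in F344 and 0.528 ± 0.147 in M520 (-3.33, SE 0.64, adjusted p = 0.0287, 66 against 5 counts). With an estimated correlation these 3 lists also had adjusted p = 0.898. Myom3 fell (-1.67, SE 0.28, adjusted p = 0.0165) among sarcomere genes, whose median of -0.21 did not pass (adjusted p = 0.214). The mitochondrial genome had a median of 0.29 (adjusted p = 0.734, with a mean of -0.06), 2 of 13 lower adjusted over the list alone and none over all genes.

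The other lists did not pass between M520 and F344, with medians of 0.17 for nuclear-encoded oxidative phosphorylation (adjusted p = 0.104), 0.01 for G1/S (0.734), 0.10 for cell cycle inhibitors and ploidy regulators (0.666), -0.07 for actomyosin and Shroom partners (0.597), and -0.08 for the intercalated disc (0.626). Calcium handling stood at 0.03 (0.732), with -0.01 for glucose metabolism (0.635, with a mean of 0.05), -0.04 for YAP targets (0.992), 0.14 for stress genes (0.552), 0.10 for extracellular matrix (0.431) and -0.08 for the genes near Shroom3 (0.626). Wall stress (median -0.11, adjusted p = 0.895) and the clock (-0.12, adjusted p = 0.544) had medians below 0 while their test pointed up. Among endothelial markers in these nuclei Kdr was higher in M520, and the list did not pass (median 0.17, adjusted p = 0.270).

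The contrast called 198 of 12550 genes, 102 higher and 96 lower in M520, and 1168 with the replicate block, where the split turned to 547 and 621. Every library left out moved the count by over 1.5 times, to 413 and 440 without BN-Lx replicates 1 and 2, 94 and 57 without F344 replicates 1 and 2, and 98 and 49 without M520 replicates 1 and 2. Of the genes named here, 4 lost their calls without F344 replicate 1, F344 replicate 2, M520 replicate 1 and M520 replicate 2 alike, with adjusted p = 0.139, 0.0780, 0.169 and 0.0635 for Ucp3, 0.263, 0.159, 0.213 and 0.358 for Tap2, 0.189, 0.280, 0.139 and 0.579 for Mki67 and the values above for Parm1. RT1-A2 lost its call without F344 replicate 1, F344 replicate 2 or M520 replicate 2 (0.0650, 0.155 and 0.218), Myom3 without F344 replicate 2 or M520 replicate 2 (0.156 and 0.301) and Lig4 without F344 replicate 2 (0.0640). The same held for Slc9a9 and Nfasc without M520 replicate 2 (0.0659 and 0.0639). The list calls for fatty acid oxidation were lost without F344 replicate 1 or M520 replicate 1 (0.0882 and 0.373) and for ribosomal proteins without F344 replicate 2 or M520 replicate 2 (0.581 and 0.280), without the stress-led cluster (0.105) or in the largest cluster alone (0.148). That for G2/M was lost without F344 replicate 1 or M520 replicate 2 (0.0537 and 0.202), and that for antigen presentation without BN-Lx replicates 1 or 2, F344 replicate 1 or M520 replicate 1 (0.0939, 0.147, 0.599 and 0.461), and in those cluster fits (0.0845 and 0.207).

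In cardiomyocyte-like nuclei of BN-Lx 47 genes were higher than in both other strains, among them Agbl4, Tpm2, Slc35c2, Hsph1 and Disc1, and 77 lower, among them Cdkl1, Plagl1, Gbp1 and Ncln. In F344 43 were higher, such as Myom3, Nfasc, Pcdh15 and Synpr, and 24 lower, such as Lig4, Eqtn and Cyp2r1. In M520 41 were higher, such as Ooep, Bckdhb, G3bp2 and Fkbp5, and 23 lower, such as Irak2, Fras1 and Cds1. Both contrasts of a strain share its libraries. In 20 simulations unchanged strains gave 0 such genes, but too few calls to test this. Whether F344 and M520 reads map to the Brown Norway reference as well as BN-Lx reads was not tested. Lost reads would also lower genes like Agbl4 and Slc35c2 in both strains.

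In fibroblast-like nuclei Klkb1, plasma prekallikrein, had 52.3 ± 1.30 CPM in F344 and no counts in BN-Lx (at least 87.4-fold higher, adjusted p = 2.2e-05). Pclo was also higher in F344 than in BN-Lx (log2 4.73, SE 0.46) and Agbl4 (-5.94, SE 0.44), the adhesion protein Ntm (-4.07, SE 0.39), the phosphatase Ptprt (-4.01, SE 0.36) and the sulfotransferase Chst3 (-3.83, SE 0.59) were lower. Gpm6a, a neuronal membrane glycoprotein, had 565 ± 27.4 CPM in M520 against 43.9 ± 12.1 in BN-Lx and 40.6 ± 5.48 in F344 (3.65, SE 0.28, and 3.77, SE 0.30). Mycbpap was higher in M520 than in BN-Lx (3.59, SE 0.55), where Agbl4 (-6.36, SE 0.44), Ntm (-3.26, SE 0.36) and Kl (-2.96, SE 0.50), the co-receptor klotho, were lower. Zbtb16 was higher in M520 than in F344 (4.09, SE 0.49, 3242 ± 1357 against 199 ± 167 CPM, adjusted p = 5.1e-04), as was Albfm1 (3.61, SE 0.66). Klkb1 (at least 48.4-fold), Cyp2j4 (-3.09, SE 0.44), Palm2 (-2.89, SE 0.31) and Pclo (-2.72, SE 0.40) were lower. RT1-CE5, RT1-CE12, RT1-A2 and Prp2l1 were also higher, and RT1-CE16 lower, with reads that related copies can share. Without F344 replicate 2, Chst3 (adjusted p = 0.139), Cyp2j4 (0.149) and Albfm1 (0.340, and 0.0637 without F344 replicate 1) lost their calls, as did Kl without M520 replicate 2 (0.156).

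Antigen presentation genes lay higher in fibroblast-like nuclei of F344 (median 1.06, camera adjusted p = 3.1e-08) and M520 (0.65, adjusted p = 6.6e-09) than of BN-Lx. Extracellular matrix genes lay lower in both (medians -0.19 and -0.18, adjusted p = 0.0262 and 0.0104), with the collagens Col4a1 and Col5a2 called lower in F344 and periostin, Postn, in M520. Stress genes lay lower in M520 than in BN-Lx (median -0.38, adjusted p = 1.0e-05, with Dnajb1 called) and than in F344 (-0.47, adjusted p = 7.0e-06, with Jun called), and wall stress genes lower than in BN-Lx (-0.18, adjusted p = 0.00312). Sarcomere genes were higher in F344 than in BN-Lx (median 0.91, adjusted p = 2.8e-05) and lower in M520 than in F344 (-0.74, adjusted p = 2.8e-05), beside a median cardiomyocyte marker level of 2.24% and 1.27% of the cardiomyocyte-like level in the BN-Lx hearts, 2.70% and 4.11% in F344 and 1.67% and 2.65% in M520. Calcium handling genes (0.65, adjusted p = 0.0402), the mitochondrial genome (-0.36, adjusted p = 0.0170, and 0.40, adjusted p = 0.0170, in M520 against F344) and the intercalated disc (-0.36, adjusted p = 0.0280, M520 against F344) also passed. None of these lists passed with an estimated correlation (lowest adjusted p = 0.390). A fibroblast-like cluster led by Negr1 and Gria1 held 44.6% and 78.4% of the class in BN-Lx and 1.11% to 5.37% in the other strains. Of 11280 genes, 291 (166 higher, 125 lower) were called between F344 and BN-Lx, 163 (86 and 77) between M520 and BN-Lx and 68 (35 and 33) between M520 and F344, against 2090, 574 and 760 with the replicate block. The first 2 splits turned to 87 higher and 104 lower and to 77 and 99 without BN-Lx replicate 2. Leaving out BN-Lx replicates 1 and 2, F344 replicates 1 and 2 and M520 replicates 1 and 2 in turn gave 919, 191, 141, 72, 519 and 496 for the first and 191, 207, 32, 24, 159 and 36 for the third.

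In endothelial-like nuclei Kcnt2, a sodium-activated potassium channel, had 345 ± 19.3 CPM in BN-Lx, 56.6 ± 13.7 in F344 and 4.94 ± 1.08 in M520 (M520 against BN-Lx log2 -6.07, SE 0.30, adjusted p = 7.0e-07, and against F344 -3.50, SE 0.31). Tafa2 (-6.00, SE 0.38), Agbl4 (-5.58, SE 0.39), Fam163a (-4.87, SE 0.37) and the secreted protein Scube1 (-4.52, SE 0.42) were lower in F344 than in BN-Lx, and the orexin receptor Hcrtr2 (5.68, SE 0.63) and Klkb1 (ratio 380.1, interval 67.3 to 15100) higher. Nxph1, a neurexin ligand, had 220 ± 73.5 CPM in M520 against 4.56 ± 5.77 in BN-Lx and 3.95 ± 3.89 in F344 (5.27, SE 0.54, and 5.42, SE 0.61). Agbl4 (-5.16, SE 0.35), Nwd2 (-3.68, SE 0.29) and Fam163a (-3.67, SE 0.31) were lower in M520 than in BN-Lx. Fat1, an atypical cadherin, had 115 ± 15.7 CPM in F344 and 4.87 ± 0.716 in M520 (-4.57, SE 0.31). Zbtb16 was higher in M520 than in F344 (4.43, SE 0.50, 1847 ± 479 against 93.1 ± 82.6 CPM). Klkb1 (at least 79.2-fold) and Hcrtr2 (ratio 0.00663, interval 1.7e-04 to 0.0378) were lower. Gvinp1 (at least 160.1-fold in F344 and 142-fold in M520 over BN-Lx), Cd36-ps1, RT1-T24-3, RT1-N2 and RT1-CE14 were higher with reads that copies can share.

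Antigen presentation and interferon genes were higher in endothelial-like nuclei of M520 than of BN-Lx, with a median of 1.27, 25 of 26 above 0 and camera adjusted p = 2.0e-33. Of them 11 rose, among them B2m, Irf7, Ifit3, Mx1 and Mx2, and 1 fell, and 21 rose and 1 fell adjusted over the list alone. Between F344 and BN-Lx the median was 1.02 (adjusted p = 5.9e-13), with 6 higher and 1 lower, and 16 higher and 1 lower adjusted over the list alone. Between M520 and F344 it was 0.07 (adjusted p = 0.0187). Ribosomal protein genes lay higher in M520 than in BN-Lx (0.50, adjusted p = 0.0019) and F344 (0.85, adjusted p = 3.5e-05), extracellular matrix lower than in BN-Lx (-0.23, adjusted p = 0.0479) and G2/M lower than in F344 (-0.95, adjusted p = 0.0479, with Mki67 called). The mitochondrial genome lay lower in F344 than in BN-Lx (-0.46, adjusted p = 0.00347) and higher in M520 than in F344 (0.56, adjusted p = 0.00347). Sarcomere genes had medians of 0.82 (F344 against BN-Lx, adjusted p = 1.9e-05) and -0.97 (M520 against F344, adjusted p = 1.4e-05), beside cardiomyocyte markers at 2.43% and 0.948% of the cardiomyocyte-like level in BN-Lx, 2.68% and 3.81% in F344 and 1.48% and 2.44% in M520. None passed with an estimated correlation (lowest adjusted p = 0.481). Of 11692 genes, 289 (151 higher, 138 lower), 252 (159 and 93) and 139 (86 and 53) were called in the 3 contrasts, against 2047, 667 (326 and 341) and 1477 with the replicate block. The first split turned to 523 higher and 594 lower without BN-Lx replicate 1 and to 65 and 83 without BN-Lx replicate 2. The largest cluster held 51.1% and 6.91% of the class in BN-Lx, 69.2% and 51.9% in F344 and 44.0% and 25.96% in M520, and another 24.8% and 68.0%, 5.77% and 21.7%, and 22.8% and 46.9%. The first was 1117 and 148 without BN-Lx replicates 1 and 2, 132 and 69 without F344 replicates 1 and 2 and 453 without M520 replicate 1, and the third 385, 363, 62, 31, 249 and 63 with the libraries left out in the same order.

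Pericyte-like nuclei of BN-Lx lacked Spock3, a matrix proteoglycan with 757 ± 24.7 CPM in F344 (at least 392-fold higher, adjusted p = 2.3e-11) and 738 ± 80.6 in M520 (at least 355-fold, adjusted p = 2.2e-11), and Dmp1, a matrix phosphoprotein (at least 20.5-fold and 47.2-fold higher). Zbtb16 fell in F344 against BN-Lx (-3.45, SE 0.41) and rose in M520 against F344 (4.87, SE 0.42, 2073 ± 724 against 87.6 ± 67.2 CPM, adjusted p = 2.2e-07). The BMP receptor Bmpr1b had 124 ± 69.5 CPM in M520 and no counts in F344 (at least 25.6-fold). Tafa2 was higher in M520 than in F344 (749 ± 96.0 against 42.7 ± 7.02 CPM, SE of log2 0.40) and Pld5 lower (-4.51, SE 0.42), as were Klkb1 (at least 24.1-fold) and Hcrtr2 (at least 15.6-fold). Agbl4 was lower in F344 (ratio 0.0155, interval 0.00318 to 0.0455) and M520 (-6.54, SE 0.49) than in BN-Lx, as were Cd200l2 (at least 5.73-fold, and ratio 0.0298, interval 7.4e-04 to 0.174) and, in F344, Nt5c1a (ratio 0.109, interval 0.0220 to 0.3303). Klkb1 in F344 (at least 34.5-fold) and Oca2, a melanosome transporter, in M520 (ratio 56.5, interval 15.1 to 474) were higher than in BN-Lx. Gvinp1 (at least 51.2-fold and 33.8-fold over BN-Lx), RT1-CE16 and Abcg3l3 changed with reads that copies can share. Cd200l2 lost its call in F344 without BN-Lx replicate 2 (adjusted p = 0.137), F344 replicate 1 (0.0831) or F344 replicate 2 (0.304) and in M520 without BN-Lx replicate 2 (0.0701) or M520 replicate 2 (0.413). Nt5c1a lost it without BN-Lx replicate 2 (0.106) or F344 replicate 2 (0.447) and Hcrtr2 without F344 replicate 1 (0.0920) or M520 replicate 2 (0.306).

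Sarcomere genes had medians of 1.17 (F344 against BN-Lx, camera adjusted p = 3.7e-08, with Tnnt2 and Ttn called higher) and -1.17 (M520 against F344, adjusted p = 2.6e-10, with Ttn called lower) in pericyte-like nuclei, beside cardiomyocyte markers at 2.59% and 1.13% of the cardiomyocyte-like level in BN-Lx, 3.72% and 3.99% in F344 and 1.74% and 2.32% in M520. Antigen presentation genes lay higher in F344 (1.36, adjusted p = 4.3e-05) and M520 (0.93, adjusted p = 0.0180) than in BN-Lx. Stress genes lay lower in M520 than in BN-Lx (-0.49, adjusted p = 3.3e-04, with Hsph1 called) and F344 (-0.28, adjusted p = 0.0180, with Klf4 called). Clock genes lay higher in M520 than in F344 (0.63, adjusted p = 0.00256, with Per1 called) and the mitochondrial genome lower in F344 than in BN-Lx (-0.48, adjusted p = 0.0321). None passed with an estimated correlation (lowest adjusted p = 0.795). Of 7484 genes, 97 (49 higher, 48 lower), 97 (52 and 45) and 59 (33 and 26) were called, against 814, 281 and 724 with the replicate block. The first was 416 without BN-Lx replicate 1, 49 and 48 without F344 replicates 1 and 2 and 161 without M520 replicate 1, the second 48 without M520 replicate 2, and the third 194, 192, 26, 21, 111 and 19 with the libraries left out in turn.

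In macrophage-like nuclei Clec4e, a receptor for mycobacterial glycolipid, had no counts in BN-Lx and was at least 10.8-fold higher in F344 and 13.3-fold in M520. Gria2 was lower in M520 than in BN-Lx (-5.65, SE 0.64, from 491 ± 259 to 11.9 ± 11.6 CPM), and Elovl6 (-3.54, SE 0.59) and Map3k13 (-3.53, SE 0.71) in F344. Fkbp5 was higher in M520 than in F344 (3.55, SE 0.46, 440.4 ± 259 against 37.7 ± 1.02 CPM, adjusted p = 4.3e-05), as were Hs6st3 (3.67, SE 0.65) and Tafa2 (ratio 33.4, interval 5.57 to 1362). The inflammasome sensor Naip6 (-3.62, SE 0.49) and Pira2 (-3.14, SE 0.48), both of gene families with close copies, were lower. Agbl4 was lower in F344 (-4.79, SE 0.58) and M520 (-5.05, SE 0.61) than in BN-Lx, and Ms4a6c in M520 (ratio 0.0589, interval 0.00685 to 0.230, and adjusted p = 0.0503 with the block against 0.0251 without). Klkb1 (at least 27.9-fold over BN-Lx and 28.75-fold over M520) was higher in F344, and Nxph1 (at least 8.75-fold) and Vwa7 (ratio 31.1, interval 5.20 to 1266) in M520 over BN-Lx. Without BN-Lx replicate 2 the calls against BN-Lx were lost for Clec4e (adjusted p = 0.196 in F344 and 0.115 in M520), Elovl6 (0.0774), Map3k13 (0.606), Nxph1 (0.543), Vwa7 (0.196) and Ms4a6c (0.128). Without BN-Lx replicate 1 they were lost for Nxph1 (0.107) and Ms4a6c (0.243), without F344 replicate 2 for Clec4e (0.0564) and Map3k13 (0.0566), without M520 replicate 1 for Nxph1 (0.217) and Tafa2 (0.108), and without M520 replicate 2 for Nxph1 (0.209), Vwa7 (0.119), Ms4a6c (0.390) and Pira2 (0.0812).

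Stress genes lay lower in macrophage-like nuclei of F344 (median -0.67, camera adjusted p = 5.9e-07, with Nr4a3 and Hsph1 called) and M520 (-0.32, adjusted p = 0.0037) than of BN-Lx. They lay higher in M520 than in F344 (0.32, adjusted p = 0.0496). Antigen presentation genes lay higher in F344 (0.94, adjusted p = 3.3e-08) and M520 (0.90, adjusted p = 3.4e-08) than in BN-Lx, and the mitochondrial genome lower (-0.60, adjusted p = 0.00597, and -0.34, adjusted p = 0.0496). Sarcomere genes had a median of 0.56 between F344 and BN-Lx (adjusted p = 0.0125), beside cardiomyocyte markers at 10.5% and 9.18% of the cardiomyocyte-like level in BN-Lx and 22.7% and 8.62% in F344. None passed with an estimated correlation (lowest adjusted p = 0.769). Of 8317 genes, 57 (28 higher, 29 lower), 62 (37 and 25) and 34 (23 and 11) were called, against 104 with the replicate block for the first. The first was 31 without BN-Lx replicate 2 and 110 without F344 replicate 2, the second 31 (9 higher and 22 lower) without BN-Lx replicate 2 and the third 14 without M520 replicate 2.

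Between F344 and BN-Lx, 186 of the genes called in cardiomyocyte-like nuclei were tested in fibroblast-like nuclei, where 148 had the same sign. There 54 were also called, 50 of them with the same sign (Fisher's exact p = 8.8e-48). Called in all 5 classes were Slc35c2, Agbl4, Ncln, Klkb1, RT1-CE5, RT1-A3 and RGD1565355 between F344 and BN-Lx, with Ncln, an endoplasmic reticulum protein, 1.49 to 1.98 log2 higher in F344. Between M520 and BN-Lx they were Slc35c2, Agbl4, RT1-CE16, Bckdhb (2.06 to 2.57), Gpm6a, RT1-T24-3 and RGD1565355, and between M520 and F344 Zbtb16, Fkbp5, Bckdhb, RT1-A2, Klkb1 and the zinc finger gene Zcchc9 (-2.63 to -1.54). These classes come from the same hearts, and their genes are not independent of each other.

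RNA content per nucleus was compared as the ratio of median UMIs in cardiomyocyte-like nuclei to those in all other named nuclei of a library, a value that ploidy could move among other things. The ratio was 3.44 and 1.40 in the BN-Lx hearts, 3.14 and 3.61 in F344 and 2.17 and 2.47 in M520, with means of 2.42 ± 1.44, 3.37 ± 0.334 and 2.32 ± 0.211 (SD, n = 2). With the stricter nuclei filter the means were 2.001, 1.91 and 1.70, so that F344 was no longer the highest (exact permutation p = 0.667). Without the low-UMI cardiomyocyte-like cluster the BN-Lx mean was 2.80 ± 0.934 (exact permutation p = 0.467). Cardiomyocyte-like nuclei had medians of 3143 and 3176 UMIs in BN-Lx, 2566 and 3411 in F344 and 1963 and 4199 in M520. An exact permutation test gave p = 0.533, from 8 of the 15 splits, and the smallest p this test allows is 0.0667, so that it could not have told strains apart. Without BN-Lx replicate 1 the exact p was 0.0667, without BN-Lx replicate 2 0.2 and otherwise 0.533 to 0.8. No DNA content was measured in these files.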

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

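Tests for a difference between cardiomyocyte-like and endothelial-like nuclei were planned, and the nuclei set apart below were looked at only after the clusters had been seen. Fat1, an atypical cadherin, was higher in endothelial-like nuclei of F344 than of BN-Lx (log2 4.30, adjusted p = 1.3e-05) and not called in cardiomyocyte-like nuclei (-0.58, adjusted p = 0.285), a difference of -4.78 between the classes (SE 0.25, adjusted p = 5.1e-11). Between M520 and F344 the same gene gave 4.80 (SE 0.28), from 0.26 in cardiomyocyte-like and -4.57 in endothelial-like nuclei. Irak2 was lower in cardiomyocyte-like nuclei of M520 than of either other strain with little change in endothelial-like nuclei. The classes differed by -3.76 against BN-Lx (SE 0.27, from -4.37 and -0.58) and by -3.87 against F344 (SE 0.29, from -3.59 and 0.26). Pkia, an inhibitor of protein kinase A, was higher in endothelial-like nuclei of M520 than of BN-Lx (3.44) and stood at 0.06 in cardiomyocyte-like nuclei, a difference of -3.32 (SE 0.27).

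Slc9a9, a sodium-proton exchanger, differed by 3.88 between the classes for F344 against BN-Lx (SE 0.31, from 2.54 in cardiomyocyte-like and -1.25 in endothelial-like nuclei), and Gabrb1, a GABA receptor subunit, by 5.19 for M520 against BN-Lx (SE 0.47, from 3.80 and -0.98). Gngt2, a G protein subunit, differed by -4.02 for M520 against F344 (SE 0.37, from -2.89 and 1.05). Cdkl1 gave 7.98 for F344 against BN-Lx (SE 0.65, from 6.39 and -1.76), where the BN-Lx cardiomyocyte-like nuclei held only 3 counts and the size of the fold depends on the count added to each library before the logarithm. In all, 378 of 13701 genes differed between the 2 classes for F344 against BN-Lx (206 higher and 172 lower in cardiomyocyte-like nuclei), 270 for M520 against BN-Lx (154 and 116) and 224 for M520 against F344 (99 and 125). With DESeq2 size factors the splits were 168 and 204, 150 and 127, and 112 and 118, so that the direction of the first split depends on the scaling. With a term for replicate number by class, chosen after the data had been seen, the counts were 444 (237 and 207), 311 (175 and 136) and 274 (123 and 151), and 364, 264 and 222 of the calls were kept.

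The first count was 696 (247 higher and 449 lower) without BN-Lx replicate 1, where the direction turned, and 64 without F344 replicate 2. The second was 485 (179 and 306), turned as well, without BN-Lx replicate 1 and 86 without M520 replicate 2. The third was 528 and 553 without BN-Lx replicates 1 and 2, 53 without F344 replicate 2, and 143 and 77 without M520 replicates 1 and 2.

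Nuclei with genes of cell division lay outside the named classes. This cluster of 176 nuclei was led by Cenpf, Mki67 and Top2a, and it stayed unnamed because fewer than 3 markers of any type were up. It held 52 and 26 nuclei of the BN-Lx hearts, 29 and 26 of F344 and 24 and 19 of M520. Mki67 stood at 1459 CPM in it against 2.55 CPM in cardiomyocyte-like nuclei. The endothelial marker Pecam1 reached 1405 CPM, the leukocyte marker Ptprc 50.6 and the fibroblast marker Pdgfra 45.7, while the cardiomyocyte marker Ryr2 had 1218 CPM and cardiomyocyte markers a median of 7.65% of their cardiomyocyte-like level. Which types of cell make up the cluster, and whether strains differ in it, was not tested.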

How the results depend on the processing

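Fits without single cardiomyocyte-like clusters and with replicate number by class were chosen after the data had been seen, and the other alternatives were planned. The named genes other than Shroom3 gave 313 results, 163 of them called, and of their 5573 values under alternatives 5165 kept their direction and side of the threshold, 159 lost a call, 243 gained one and 6 changed sign. Of 243 values for Shroom3, 216 kept both, 7 gained a call and 20 changed sign. The calls kept were 162 of 163 with DESeq2 size factors, 146 of 163 with the DESeq2 Wald test (7 with no adjusted p), 133 of 146 with the stricter nuclei filter and 136 of 163 without M520 replicate 2. Of 127 values for 10 called list results 81 kept their call and 46 lost it, of 66 for 6 called class shares 34 kept and 32 lost it, and of 33 for the UMI ratio 29 stayed within 1 SD and 4 moved. The replicate block ended the calls of Ms4a6c and of 3 lists between M520 and F344 and changed no other call of a gene, class share or cardiomyocyte-like list named here except by adding calls. Lists in the other classes were not run with the block. In macrophage-like nuclei it kept 56 of 62 calls for M520 against BN-Lx and 33 of 34 for M520 against F344. The cause was not tested for any change below, beyond fewer genes tested under a filter and fewer libraries.

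Without a filter on low counts the calls were 720, 567 and 486 in cardiomyocyte-like nuclei for F344 against BN-Lx, M520 against BN-Lx and M520 against F344, 653, 298 and 191 in fibroblast-like and 886, 480 and 556 in endothelial-like nuclei, 173 and 105 in pericyte-like nuclei for F344 against BN-Lx and M520 against F344 and 94 in macrophage-like nuclei for F344 against BN-Lx. With the CPM filter pericyte-like nuclei gave 175 and 115 for those contrasts. With the replicate block the calls were 1733, 1041 and 1168 in cardiomyocyte-like, 2090, 574 and 760 in fibroblast-like, 2047, 667 and 1477 in endothelial-like and 814, 281 and 724 in pericyte-like nuclei, and 104 in macrophage-like nuclei for F344 against BN-Lx. Fitted with only the strains compared, M520 against F344 gave 380, 170, 265 and 235 calls in cardiomyocyte-like, fibroblast-like, endothelial-like and pericyte-like nuclei.

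Thinned to equal depth, cardiomyocyte-like nuclei gave 121 calls for M520 against F344, fibroblast-like nuclei 154 and 101 for the contrasts with BN-Lx, endothelial-like and pericyte-like nuclei 150 and 43 for M520 against BN-Lx, and macrophage-like nuclei 41 for M520 against BN-Lx and 18 for M520 against F344. With the stricter nuclei filter fibroblast-like nuclei gave 146 and 95 for the contrasts with BN-Lx and macrophage-like nuclei 17, 15 and 11. With classes set by marker score fibroblast-like nuclei gave 157 for F344 against BN-Lx and 27 for M520 against F344, endothelial-like nuclei 167 and 162 for the contrasts with BN-Lx, pericyte-like nuclei 204 for F344 against BN-Lx and macrophage-like nuclei 34, 31 and 19. The DESeq2 Wald test gave 57, 57 and 36 in pericyte-like and 25, 35 and 18 in macrophage-like nuclei, and macrophage-like nuclei with doublet calls kept gave 105 for F344 against BN-Lx.

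With a library left out, the calls for F344 against BN-Lx ranged from 137 to 453 in cardiomyocyte-like, 72 to 919 in fibroblast-like, 69 to 1117 in endothelial-like, 48 to 416 in pericyte-like and 31 to 110 in macrophage-like nuclei. For M520 against BN-Lx they ranged from 97 to 403, 127 to 231, 183 to 265, 48 to 115 and 31 to 89 in the same order. For M520 against F344 they ranged from 49 to 440, 24 to 207, 31 to 385, 19 to 194 and 14 to 44. Genes that differed between cardiomyocyte-like and endothelial-like nuclei ranged from 64 to 696, 86 to 485 and 53 to 553, and the exact p of the UMI ratio from 0.0667 to 0.8.

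The lists called were 4, 2 and 4 of 19. With an estimated correlation or fry they were 0, 0 and 0 (lowest adjusted p = 0.898 and 0.310). For M520 against F344 they were 1 with the replicate block, without the stress-led cluster and in the largest cluster alone. For M520 against BN-Lx they were 1 without the stress-led cluster. With a library left out they ranged from 3 to 7, 2 to 4 and 2 to 4. For F344 against BN-Lx sarcomere genes passed upwards without BN-Lx replicate 1 (adjusted p = 0.00364) and downwards without BN-Lx replicate 2 (0.0326). Without the latter fatty acid oxidation passed upwards (0.0389) and the clock downwards (0.0489). Extracellular matrix passed downwards without F344 replicate 2 as well (0.04995), ribosomal proteins without F344 replicate 1 (0.02065) and the mitochondrial genome without F344 replicate 2 (0.0293). For M520 against BN-Lx extracellular matrix passed downwards without BN-Lx replicate 1 (2.5e-06), sarcomere (1.1e-05) and wall stress (1.5e-04) without BN-Lx replicate 2, and calcium handling in the largest cluster alone (0.0315). For M520 against F344 sarcomere genes passed downwards without BN-Lx replicate 2 (0.0379), F344 replicate 2 (0.04995) or M520 replicate 1 (0.0262), oxidative phosphorylation upwards without F344 replicate 1 (0.0106) or M520 replicate 1 (0.0262) and stress genes upwards without F344 replicate 1 (0.0106). The G2/M list gave no value without F344 replicate 2, without the cluster led by stress genes or in the largest cluster alone, where fewer than 5 members were tested.

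The classes whose shares were called were 2, 0 and 1 with the stricter nuclei filter, 4, 2 and 3 with TMM over classes, 2 and 2 with the replicate block, 3 and 4 with doublet calls kept, and 3 for M520 against BN-Lx with marker scores. With a library left out they ranged from 1 to 3 for F344 against BN-Lx and from 0 to 2 for M520 against BN-Lx.

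Shroom3 in cardiomyocyte-like nuclei passed for M520 against F344 with the replicate block (-0.48). In fibroblast-like nuclei it changed sign with the stricter nuclei filter (0.22, 0.49 and 0.27 in the 3 contrasts) and with marker scores (0.18 and 0.0469 in the contrasts with BN-Lx), and ranged from -0.67 to 0.14 and, for M520 against F344, from -0.37 to 0.43 with a library left out. In endothelial-like nuclei M520 against BN-Lx gave 0.16 and 0.30 under those settings, and M520 against F344 passed without a filter (-1.42) and with the replicate block (-1.50). With a library left out, endothelial-like values ranged from 0.22 to 1.99, -1.12 to 0.55 and -1.78 to -0.62. In pericyte-like nuclei F344 against BN-Lx passed with the replicate block (1.38), and M520 against BN-Lx gave 1.09 with marker scores and -0.43 to 0.63 with a library left out. In macrophage-like nuclei M520 against F344 gave -0.23 thinned, -0.24 with doublet calls kept and -0.0173 with marker scores. With a library left out the 3 contrasts ranged from -0.0287 to 1.22, -0.16 to 1.24 and -0.85 to 0.82.

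Among genes not called, Egr1 for F344 against BN-Lx stood at 0.0875 without the cluster led by stress genes and 0.55 in the largest cluster alone, and Mki67 for M520 against BN-Lx at 0.47 in the latter. With a library left out Btg2 ranged from -1.28 to 0.00815 (F344 against BN-Lx), Incenp from -1.15 to 1.00 and Myl9 from -2.73 to 0.0845 (M520 against BN-Lx), each above 0 only without BN-Lx replicate 1.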

Other observations

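The tests below were chosen after a first look at the data had shown these patterns, and the bound for each was written before its own value was computed. In cardiomyocyte-like nuclei the targets of the glucocorticoid receptor other than Fkbp5, Zbtb16 and Tsc22d3 had a median of 0.45 for M520 against F344 (camera p = 1.2e-05, and p = 0.0514 with an estimated correlation). Among 23 such genes 16 were above 0 and 4 were called, the insulin signalling subunit Pik3r1 (log2 1.80, SE 0.25, adjusted p = 0.00527), Arrdc2 (1.95, SE 0.34, adjusted p = 0.0192), the transcription factor Foxo3 (1.43, SE 0.25, adjusted p = 0.0185) and the metallothionein Mt1 (1.42, SE 0.30, adjusted p = 0.0471). Klf9 stood at 1.08 (adjusted p = 0.0504) and Angptl4 at -1.66 (adjusted p = 0.372).

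Clock genes differed between libraries of replicate numbers 1 and 2. In cardiomyocyte-like nuclei, fitted with strain and replicate number, Bmal1, an activator of the clock, was 1.18 log2 higher in replicate 2 (adjusted p = 0.00133), and the repressor Per2 (-1.09, adjusted p = 0.00227) and the clock output factor Dbp (-0.94, adjusted p = 0.00633) were lower. In this fit 1813 cardiomyocyte-like genes were called for replicate number (849 higher and 964 lower in replicate 2), 1251 fibroblast-like, 505 endothelial-like and 494 pericyte-like genes, and edgeR called 0 macrophage-like genes.

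The first pattern weighed is the lower level of Fkbp5, Zbtb16 and, as a call in 2 of 5 classes, Tsc22d3 in F344 than in M520. A larger share of stressed nuclei in 1 strain is argued against, since Fkbp5 and Zbtb16 kept at least 0.990 of their log2 difference without the cluster led by stress genes (2.88 to 2.90 and 2.74 to 2.71). Less receptor activity in F344 predicted lower levels of the other targets, whose median for F344 against M520 was -0.45 in cardiomyocyte-like nuclei and below 0 in 5 of 5 classes. The camera p was 3.1e-05 in macrophage-like (0.0900 with an estimated correlation), 0.0668 in fibroblast-like, 0.122 in endothelial-like and 0.209 in pericyte-like nuclei. It stays open as a hypothesis. Another time of day at collection stays open too, because evening minus morning clock genes differed by -0.80 log2 while the libraries overlapped (-0.57 and -1.63 in F344, 0.29 and -0.88 in M520). Compared within replicate numbers, which was done after these values had been seen, F344 lay below M520 in both pairs of hearts in each of the 5 classes, which share those 4 hearts, by -0.86 and -0.75 in cardiomyocyte-like but only -0.07 and -0.68 in fibroblast-like and -0.31 and -1.11 in macrophage-like nuclei. The 2 cannot be told apart with 2 hearts per strain. Hormone levels and the strains' genotypes were not tested.

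The second pattern is that genes called in cardiomyocyte-like nuclei lie beside each other. Of 450 called genes with a place, 75 had a called neighbour against 33.4 in random draws (20 to 49, permutation p = 1e-04, the smallest that 10000 draws allow), and the longest run was RT1-CE15, RT1-CE12, LOC120098829, RT1-CE5 and RT1-CE4. Without neighbours that share a name stem or have only a placeholder name the number was 38, within the 15 to 42 of random draws (permutation p = 0.0968), which is consistent with reads shared between copies of a gene family. A shared regulatory variant or a duplicated segment that differs between strains would give the same neighbours and stays open, untested.

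The third pattern is that libraries of the same replicate number deviate alike. A different share of stressed cardiomyocyte nuclei is argued against, since 1789 genes called for replicate number kept a median of 0.938 of their difference in the largest cluster alone (quartiles 0.865 to 1.01). Another time of day at collection predicted higher evening minus morning values in replicate 1 outside cardiomyocyte-like nuclei. This held in every strain in 4 of 4 classes (fibroblast-like 0.79 to 1.54 log2, endothelial-like 0.49 to 0.84). All come from hearts that had shown it in cardiomyocyte-like nuclei, so this is not independent. Time of day stays open as a hypothesis, as does a shared day of library preparation, untested and not in the labels.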
